A study of Mus musculus with 12 samples.

How the data were processed

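The series holds 12 RNA-seq libraries of wild-type mouse epididymis, 2 for each of 6 groups: segments 1, 2 and 3 after efferent duct ligation and the same segments of control tissue. Per the labels, each library was made from 500 ng of RNA with a directional kit after selection of polyadenylated RNA, and each is a pool of 2 mice. Sequencing was done in 2 batches, 3017 and 3097, and each batch holds 1 library of every group, so batch is crossed with group. The deposited tables name columns by group and come as a table per batch; libraries are therefore named by group and batch, and the replicate numbers in the labels were not tied to batches. Whether ligated and control tissue, or the segments of a pool, came from the same mice is not given in the sources used here, nor is the time after ligation.

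The authors deposited raw read counts per gene, which are whole numbers with no normalization. Per the submitters' processing notes, reads were handled with Trim Galore 0.6.0, cutadapt and FastQC and with the aligner STAR 2.7.0e, on GRCm38 (mm10). The counting tool, its strand setting and the annotation release are not given in the sources used here. All 55536 gene identifiers of each table match GENCODE mouse release 21 on GRCm38, so coordinates are given from that annotation. No line lacked a gene identifier. Because the strand setting is unknown, counts of antisense genes and of overlapping genes are uncertain, and reads shared between close paralogs (the Defb, Lcn, Spink, Cst and Rnase families) may have been split or dropped.

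Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 19213 genes, and library sizes were scaled by TMM. A quasi-likelihood model (glmQLFit with robust dispersion, glmQLFTest, two-sided) with group and sequencing batch was fitted to all 12 libraries at once, so the groups share an estimate of the spread. Residual degrees of freedom were 5, the median prior degrees of freedom 4.55 and the common biological coefficient of variation 0.153. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were ligated against control in each segment, each pair of control segments, each pair of ligated segments, and the difference of the ligation effect between segments. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Batch entered the model as a block because the design text gives it: deviations from the group means of libraries of the same batch correlated between groups at -0.02 to 0.72, highest between ligated segments 2 and 3, and 1798 genes differed between batches. Within-batch log2 ratios use CPM plus 0.5.

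Levels are TMM-scaled CPM (edgeR), given as mean ± SD of 2 libraries. Totals were 30.5 to 42.3 M counts per library. A floor of 3 counts, taken per library, is worth 0.071 to 0.098 CPM before TMM scaling. Where a group had no counts, the fold is given as a lower bound against this floor after TMM scaling. Where a group had 1 to 3 counts in all, a ratio with a 95% exact interval of the counts is given. Shares carry exact Clopper-Pearson 95% intervals, which treat genes as independent although all were measured in the same libraries. Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. Replicates of a group differed by more than sampling noise in every group: chi-square per degree of freedom was 24.7 to 129.3.

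Before the data were examined, 35 gene lists were fixed, from initial segment genes and ERK targets to markers of the cell types that such tissue can hold, with 18 sentinel genes chosen whatever their result. For each ligation contrast, the 34 lists with at least 4 measured members were compared with all other genes by limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists; the adipocyte list was too short. A preset correlation ignores how strongly the members of a list vary together between pools, so camera with the estimated correlation and fry were run as alternatives. No camera call held with the estimated correlation. The signs of a list's median, mean and test differed in 10, 5 and 6 of the 34 lists in segments 1, 2 and 3, and 0 of these were called. In segment 1 they were beta-defensins, androgen response, hypoxia and glycolysis, B cells, basal cells, general epithelium, smooth muscle, blood, fluid and ion transport, and growth factor signalling. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

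Named genes were chosen by a rule fixed in advance. For each ligation contrast it takes the 8 largest and the 8 smallest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group, the same direction in both batches, and a symbol that is not of the Gm-number, Rik or -ps type. The clone-style name AC132367.1 matches none of these patterns and stayed in. It adds the 18 sentinels and, for each list described, up to 4 called members with the smallest adjusted p. For control pairs and for differences between segments it takes 5 in each direction. Genes named outside the rule are said to have been chosen after their values were seen. Some genes that the rule names are not used here.

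The alternatives were RLE size factors, library totals alone, genes above 1% of a library left out of library sizes (9 genes), no low-count filter (33148 genes), a filter of 1 CPM in at least 2 libraries (15515 genes), DESeq2 1.42.0 with batch in the model, no batch term, only the libraries of the groups compared, an added minimum of 1 on the absolute log2 fold change, control differences of at least 1 log2 for the shares kept, and each library left out in turn. A group left with 1 library is then assumed to vary like the others. A fit of all groups without the segment 2 control library of batch 3017 was added after seeing the data. The fitting was tested on simulated counts of 18501 genes with known changes in a small part of them. For ligation in segment 1 these were 64 genes at 1.5-fold, 65 at 2-fold and 66 at 4-fold. For ligation in segment 1 the fit recovered 23.4% of 1.5-fold, 63.1% of 2-fold and 80.3% of 4-fold changes, with 3.5% false calls among 113. For segment 2 the shares were 23.4%, 54.1% and 81.2%, and for segment 3 26.2%, 59.1% and 70.3%. For the difference of the ligation effect between segments 1 and 2 they were 4.7%, 33.3% and 69.2%. False calls over the 9 contrasts simulated were 2.7% to 7.2%, above 5% for ligated segments 2 against 3 (6.9%) and for the difference in effect between segments 1 and 3 (7.2%). The list test found the raised list and called 0 of 50 unchanged lists of random genes. The simulation held no batch effect, no correlation between genes and far fewer changed genes than were called in segment 1. Each simulated gene took its spread from a trend over expression level, the same in all groups. The real groups differed in spread, with a chi-square per degree of freedom of 24.7 in ligated segment 1 and 129.3 in control segment 2. The simulated rates may therefore not carry over to the real data, and the simulation cannot test correlation within a list. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Every deposited column was used.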

Results

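Polyadenylated RNA was measured in the 3 most proximal segments of the epididymis of wild-type mice, with and without ligation of the efferent ducts. The efferent ducts carry fluid and sperm from the testis into the epididymis, and the suture was tied where they reach its head, the caput. Segment 1, often called the initial segment, lies closest to the efferent ducts, and segments 2 and 3 follow. Each of the 6 groups held 2 libraries, 1 in each of the sequencing batches 3017 and 3097, and each library was a pool of 2 mice. P-values therefore measure the spread between pools, not between mice. Control libraries of batches 3017 and 3097 held 42.3 and 36.3 M counts in segment 1, 30.5 and 32.3 M in segment 2, and 35.2 and 39.3 M in segment 3. Ligated libraries held 40.3 and 33.0 M, 36.4 and 39.7 M, and 37.9 and 39.3 M in that order. Gpx5, which encodes a secreted glutathione peroxidase of the caput, was the most abundant gene in all 12 libraries, at 2.51% to 6.03% of counts. Mitochondrial genes took 1.57% to 2.88%. The control libraries of segment 2 stood farthest apart of any group, with a chi-square per degree of freedom of 129.3 over 16866 genes against 24.7 to 89.1 in the other groups. Levels below are mean ± SD in CPM over n = 2 libraries, log2 fold changes carry their SE, and adjusted p-values come from edgeR's quasi-likelihood test.

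The comparison of ligated with control segment 1 asked how this segment changed when the flow from the testis was stopped. Several abundant secretory transcripts fell to a small part of their control level. Lcn8, a lipocalin gene (ENSMUSG00000036449, GRCm38 chromosome 2, 25653120 to 25656217), fell from 13962 ± 378 CPM in control tissue to 14.2 ± 1.87 CPM after ligation, a log2 fold change of -9.97 ± 1.46 (adjusted p = 0.0026). Cst8, which encodes a cystatin-related protein (ENSMUSG00000027442, chromosome 2, 148798785 to 148805595), fell from 3940 ± 269 to 3.08 ± 0.557 CPM (-10.33 ± 1.34, adjusted p = 0.0016). Other genes rose. Clu, encoding the chaperone clusterin (ENSMUSG00000022037), went from 508 ± 78.6 to 17473 ± 1725 CPM (5.14 ± 0.65, adjusted p = 8.7e-04). Spink11, of the serine protease inhibitor family (ENSMUSG00000073573, chromosome 18, 44190045 to 44196177), went from 3.90 ± 1.27 to 684 ± 67.3 CPM (7.53 ± 1.59, adjusted p = 0.012).

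Of 19213 genes tested, 9363 (48.7%) were called, 4684 higher and 4679 lower after ligation, and 9362 of them had the same direction in both batches. At least 2-fold changes made up 4396 of the calls, 2599 higher and 1797 lower. DESeq2 called 8667. Scaling by library totals alone moved the median of all genes by 0.202 on the log2 scale and the split to 6505 higher and 3130 lower, so changes here are relative to TMM scaling. Named genes were chosen largely for extreme fold changes or small adjusted p in this same fit, so how their calls held need not be typical of all calls. Of 152 named genes called in this segment, 138 kept their call whichever library was left out. Calls lost numbered 10 and 11 without the control libraries of batches 3017 and 3097, and 8 and 5 without the ligated ones.

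Among the lowest genes by the naming rule, 4 had no counts in either ligated library. Ntsr1, the neurotensin receptor gene (chromosome 2, 180499976 to 180544980), held 139 ± 29.97 CPM in control segment 1 and was at least 1807-fold lower after ligation. Xkr7 (chromosome 2, 153031852 to 153055775) was at least 683-fold lower and Ffar2, a receptor for short-chain fatty acids (chromosome 7, 30818348 to 30823775), at least 623-fold lower. AC132367.1, annotated as antisense (chromosome 17, 24533862 to 24546531), was at least 706-fold lower, and its counts cannot be told from those of its partner gene without the strand setting. Tecta, which encodes an extracellular matrix protein known from the inner ear (chromosome 9, 42329619 to 42399929), kept 2 counts and its ratio of control to ligated was 7886 (95% interval 2183 to 65122). Rnase10 (chromosome 14, 51007751 to 51010758) fell from 9178 ± 652 to 1.57 ± 0.122 CPM (-12.58 ± 1.16, adjusted p = 3.8e-04). Lcn9 (chromosome 2, 25823153 to 25825537) fell from 8584 ± 503 to 0.926 ± 0.0430 CPM (-13.24 ± 1.40, adjusted p = 7.3e-04). Defb48, a beta-defensin gene (chromosome 14, 62977524 to 62984510), fell from 4307 ± 227 to 0.516 ± 0.102 CPM (-13.04 ± 0.97, adjusted p = 1.6e-04).

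At the other end, Gldn, which encodes gliomedin (chromosome 9, 54286486 to 54341786), had 2 counts in control segment 1 and 28.6 ± 0.303 CPM after ligation, a ratio of 1052 (95% interval 291 to 8689; adjusted p = 0.0083). Pate4 rose by 7.45 ± 0.92 (chromosome 9, 35607093 to 35611941; adjusted p = 6.2e-04) and Defb15 by 7.29 ± 1.5 (chromosome 8, 21929799 to 21932710; 0.011). Upk1a, a uroplakin gene, rose by 7.10 ± 0.79 (chromosome 7, 30603092 to 30612847; 8.9e-04) and Cntn3 by 6.84 ± 0.70 (chromosome 6, 102162655 to 102573101; 2.3e-04). Tmem238l rose by 6.81 ± 0.69 (chromosome 11, 66956638 to 66965016; 5.2e-04). Lypd8 (chromosome 11, 58379043 to 58390728) reached 9607 ± 1766 CPM, but its control libraries held 160 counts in batch 3017 and 6399 in batch 3097 (7.13 ± 1.77, adjusted p = 0.02). Leaving out a library ended the call of some of these. Without the control library of batch 3017 the adjusted p was 0.065 for Gldn and 0.08 for Defb15. Without that of batch 3097 it was 0.083 for Spink11, and without the ligated library of batch 3017 it was 0.067 for Lypd8.

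The list of initial segment and lumicrine genes, known from that segment or from luminal signalling from testis to epididymis, fell as a group. Of 19 measured members 13 fell and 3 rose (14 and 3 adjusted over the list alone), with a median log2 fold change of -2.44 (camera adjusted p = 0.002). With an estimated correlation the adjusted p was 0.66, as for each of the 13 lists called in this segment. Ovch2, a serine protease gene, fell by 6.48 ± 0.41 (adjusted p = 4.1e-05). Ros1, the receptor tyrosine kinase gene needed for initial segment differentiation, fell by 2.11 ± 0.25 (3.4e-04). Srd5a1, encoding a 5-alpha reductase that activates testosterone, fell by 2.44 ± 0.41 (0.0028). Ggt1, a glutathione-degrading enzyme, rose by 3.36 ± 0.44 (0.0012) and Penk, the proenkephalin gene, by 1.57 ± 0.19 (2.6e-04). Rnase9 held 11.5 ± 4.58 CPM in control and 9.63 ± 0.0769 CPM in ligated tissue (-0.27 ± 2.33, adjusted p = 0.94). Crisp1, a secretory protein gene of the sperm-coating kind, fell from 878 ± 46.1 to 11.4 ± 1.87 CPM (-6.27 ± 0.89, adjusted p = 0.0023). Adam7 fell by 1.18 ± 0.18 (5.4e-04). Gpx5 (0.24 ± 0.18, adjusted p = 0.29) and Lcn5 (2.74 ± 0.97, 0.062) did not pass.

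Feedback regulators and targets of ERK signalling fell in the same comparison. Of 20 members 18 fell and 2 rose (the same counts adjusted over the list alone), with a median of -3.17 (camera adjusted p = 3.3e-07). Those that rose, named after their values were seen, were Myc and Il17rd. The transcription factor genes Etv4 and Etv5 fell from 200 ± 48.4 to 0.208 ± 0.135 CPM (-9.87 ± 0.82, adjusted p = 2.4e-04) and from 888 ± 110 to 1.81 ± 0.214 CPM (-8.97 ± 1.10, 0.0013). Dusp6, an ERK phosphatase, fell by 5.75 ± 0.49 (2.6e-04), Spry4 by 4.44 ± 0.53 (2.1e-04) and Ier3 by 4.11 ± 0.35 (7.1e-05). Spred3 fell by 3.06 ± 0.33 (9.1e-05), Spry1 by 2.89 ± 0.20 (2.2e-05) and Spry2 by 1.72 ± 0.13 (1.7e-05). Growth factor genes upstream of this pathway went both ways, with 9 of 21 higher and 6 lower (camera adjusted p = 0.52). Hbegf fell by 3.65 ± 0.24 (1.2e-05), Vegfa by 3.22 ± 0.21 (2.8e-05) and Igf1r by 3.15 ± 0.25 (7.0e-05). Tgfa rose by 2.66 ± 0.13 (5.2e-06). Immediate early genes were 3 higher and 7 lower of 16 (0.49). Egr1 fell by 2.99 ± 0.41 (8.5e-04) and Klf4 rose by 1.29 ± 0.16 (2.0e-04). Cholesterol synthesis genes fell in 14 of 22 and rose in 3 (14 and 4 adjusted over the list alone; median -0.48, camera adjusted p = 0.031). Without the ligated library of batch 3097 the adjusted p of this list was 0.082.

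Secretory genes of the caput changed in both directions. In the caput list 10 of 28 rose and 8 fell (camera adjusted p = 0.58). Spink12 went from 19.0 ± 7.16 to 899 ± 38.8 CPM (5.66 ± 0.64, adjusted p = 7.8e-04). Of 9 epididymal lipocalins 3 rose and 4 fell (0.65). Ptgds, prostaglandin D synthase, rose by 4.48 ± 0.35 (5.7e-05) and Lcn12 by 3.61 ± 0.30 (8.2e-05), whereas Lcn2 fell by 1.62 ± 0.26 (9.5e-04). Of 32 beta-defensins 7 rose and 6 fell (0.94). Among the latter Defb25 fell from 1278 ± 115 to 3.14 ± 0.172 CPM (-8.77 ± 1.02, 0.0011). Ribosomal protein genes, listed to check scaling, rose in 22 of 24 and fell in 1 (23 and 1 adjusted over the list alone; median 0.55, camera adjusted p = 3.8e-04). Rpl10a rose by 0.83 ± 0.12 (4.3e-04).

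Markers of other cell types also differed between ligated and control segment 1. Unlabelled p-values for lists are camera's. Clear and narrow cell genes, of the acid-secreting cells, rose in 10 of 15 and fell in 1 (10 and 2 adjusted over the list alone; median 1.05, camera adjusted p = 0.0046). The carbonic anhydrase gene Car12 rose by 3.49 ± 0.24 (4.2e-05), the ammonium channel gene Rhcg by 2.96 ± 0.27 (8.8e-05) and Foxi1, their transcription factor, by 2.57 ± 0.23 (1.0e-04). Fibroblast and matrix genes rose in 12 of 22 and fell in 1 (median 0.63, 0.012; the same counts adjusted over the list alone). Decorin, Dcn, rose by 1.69 ± 0.12 (1.7e-05). Ciliated cell genes rose in 10 of 20 (median 1.24, 0.0045; 10 adjusted over the list alone). Mcidas, a regulator of multiciliated cells, rose by 2.29 ± 0.28 (2.0e-04). Macrophage and dendritic cell genes rose in 9 of 25 (median 0.48, 0.044; 9 adjusted over the list alone). Cd14 rose by 2.29 ± 0.2 (3.8e-05) and Cd68 by 3.22 ± 0.51 (0.0031). The camera adjusted p of this list was 0.12 without the control library of batch 3017, 0.12 without the ligated library of batch 3097, 0.057 with library totals alone and 0.076 with the stricter low-count filter. Interferon response genes rose in 14 of 29 and fell in 2 (16 and 2 adjusted over the list alone; median 0.76, 0.0052). Irf9 rose by 1.90 ± 0.16 (4.8e-05) and the RNA sensor gene Ddx58 changed by -0.83 ± 0.11 (3.5e-04). Complement genes rose in 7 of 13 and fell in 1 (median 0.99, 0.02; the same counts adjusted over the list alone). C4b rose by 1.57 ± 0.23 (4.7e-04). Endothelial genes fell in 9 of 15 and rose in 1 (10 and 2 adjusted over the list alone; median -0.88, 0.031, and 0.051 without the ligated library of batch 3017). Plvap changed by -3.33 ± 0.39 (1.6e-04) and Flt1 by -1.97 ± 0.25 (2.2e-04). Proliferation genes fell in 14 of 25 and rose in 1 (median -1.1, 0.0041; the same counts adjusted over the list alone). Ccnb2, cyclin B2, changed by -1.73 ± 0.37 (0.004) and Mcm2, of the replication helicase, by 0.48 ± 0.08 (0.0013). Germ cell and sperm genes fell in 14 of 28 and rose in 3 (15 and 4 adjusted over the list alone; median -2.06, or -2.05 with members without counts in a group at their bound; 0.0022). Their control levels were low. The protamine genes Prm1 and Prm2 held 1.37 ± 0.130 and 3.24 ± 0.0903 CPM in control segment 1 and changed by -4.71 ± 0.56 (1.5e-04) and -4.59 ± 0.72 (0.0022).

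The remaining lists were not called in segment 1. Members rose and fell in 6 and 6 of 17 for androgen response (camera adjusted p = 0.91), 9 and 4 of 24 for p53 and apoptosis (0.52), and 7 and 8 of 24 for the unfolded protein response (0.91). They did so in 9 and 6 of 25 for oxidative stress and glutathione (0.58), 3 and 2 of 13 for cholesterol efflux (0.3), 7 and 3 of 16 for hypoxia and glycolysis (0.51), 6 and 2 of 16 for inflammatory cytokines (0.39), and 9 and 6 of 20 for fluid and ion transport (0.74). For cell types the counts were 2 and 6 of 13 for basal cells (0.39), 5 and 6 of 16 for general epithelium (0.91), and 8 and 2 of 13 for smooth muscle (0.11). For T and NK cells they were 3 and 2 of 13 (0.48), 1 and 1 of 8 for B cells (0.91), 1 and 0 of 5 for neutrophils (0.48), 1 and 2 of 7 for blood (0.98) and 5 and 1 of 10 for testis somatic cells (0.32). Of 3 adipocyte genes 2 rose and 1 fell, without a list test. For every list not called in this segment, the counts adjusted over the list alone differed from these by at most 1 in either direction. Single members of these lists changed. The glutathione transferase gene Gstm1 rose by 3.02 ± 0.18 (adjusted p = 9.5e-06), the oxysterol receptor gene Nr1h3 by 3.37 ± 0.33 (5.6e-05) and the keratin gene Krt19 by 2.93 ± 0.18 (9.6e-06). The chloride channel gene Cftr fell from 202 ± 11.5 to 36.2 ± 6.73 CPM (-2.53 ± 0.31, 7.3e-04).

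**Figure D1:**
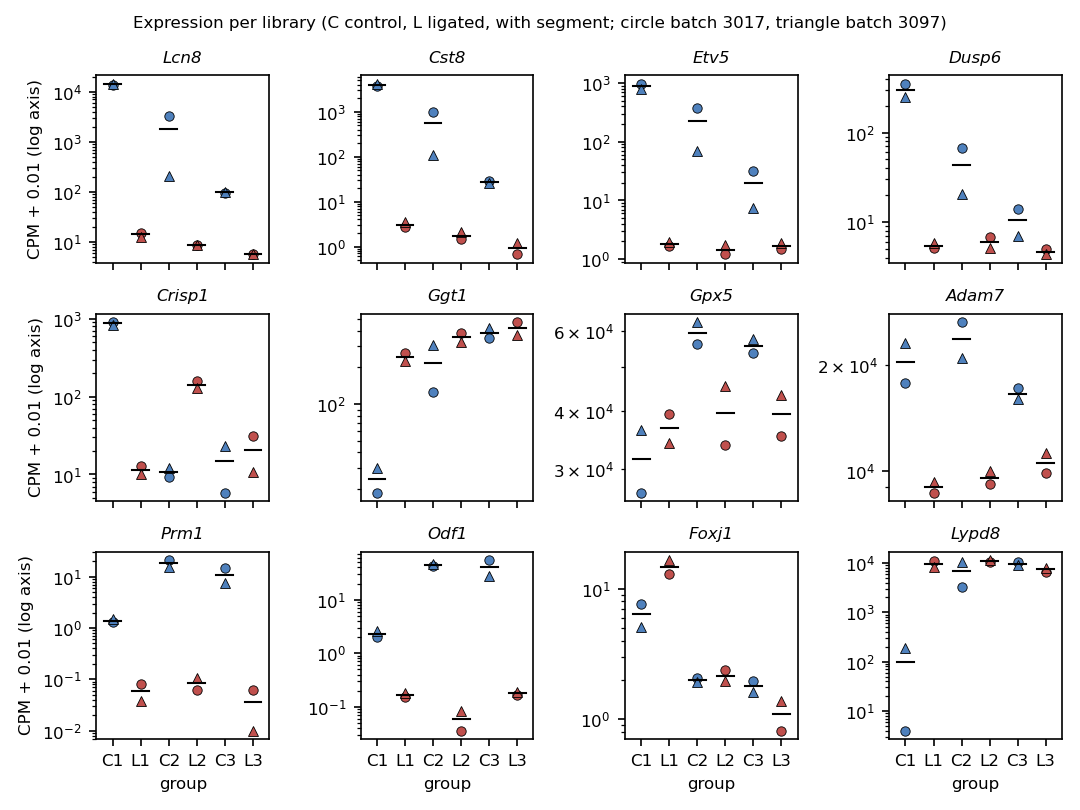
Expression of 12 genes in each library, in CPM plus 0.01 on a log axis, by group (C control, L ligated, followed by the segment); circles are batch 3017, triangles batch 3097 and bars group means. Lcn8 and Cst8 fall from 13962 and 3940 CPM in control segment 1 to 14.2 and 3.08 CPM after ligation, and their control segment 2 libraries stand far apart.

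In segment 2, ligation was followed by a fall of sperm transcripts and of genes that mark segment 1. Akap4, which encodes a scaffold of the sperm tail (ENSMUSG00000050089, chromosome X, 7067519 to 7078609), held 15.0 ± 2.52 CPM in control tissue, had no counts after ligation and was at least 199-fold lower. Prm1 (ENSMUSG00000022501, chromosome 16, 10796326 to 10805839) fell from 18.2 ± 4.08 to 0.0746 ± 0.0322 CPM (-7.84 ± 0.46, adjusted p = 1.3e-04). Crisp1 (ENSMUSG00000025431, chromosome 17, 40293758 to 40319207) rose from 10.6 ± 1.99 to 143 ± 20.4 CPM (3.74 ± 0.80, adjusted p = 0.045), while in segment 1 it had fallen.

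In all 1895 genes (9.9%) were called in segment 2, 551 higher and 1344 lower after ligation, 1892 with the same direction in both batches. At least 2-fold changes numbered 1068, 217 higher and 851 lower. DESeq2 called 2538, and scaling by library totals alone, which moved the median by 0.13, gave 1598 higher and 1071 lower. Without the batch block 1162 genes were called, and in a fit of only these 4 libraries 149. Without the control library of batch 3017 the count was 650 and without that of batch 3097 it was 4066. Without the ligated libraries of batches 3017 and 3097 it was 148 and 331. Of 87 named genes called, 15 kept their call whichever library was left out. They were Akap4, Irgc1, Spem2, Hspb9, Prr30, Spata21, Spert, Odf1, Prm1, Prm2, Tnp2, Gapdhs, Pgk2, Spry2 and Tgfa. Calls lost numbered 41 and 5 without the control libraries of batches 3017 and 3097, and 70 and 58 without the ligated ones.

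Germ cell and sperm genes fell in 20 of 28 members and rose in 0 (20 and 1 adjusted over the list alone). Their median was -5.82, or -5.33 with members without counts in a group at their bound (camera adjusted p = 7.8e-17, and 0.2 with an estimated correlation). Outside that list but among the lowest genes by the naming rule, Irgc1 (at least 88.0-fold lower), Spem2 (74.9), Hspb9 (73.0), Spata21 (72.0), Prr30 (69.3) and Spert (69.2) had no counts in the ligated libraries. Of the list, Odf1, of the outer dense fibres of the sperm tail (chromosome 15, 38219203 to 38226735), fell from 44.6 ± 3.8 to 0.0495 ± 0.0333 CPM (-9.71 ± 0.53, adjusted p = 1.8e-04). Prm2 fell by 8.68 ± 0.65 (0.0014). Tnp2, a transition protein gene, changed by -8.29 ± 0.53 (1.6e-04) and Gapdhs, the sperm glycolytic enzyme, by -7.2 ± 0.37 (1.1e-04). Proliferation genes fell in 11 of 25 and rose in 0 (18 and 0 adjusted over the list alone; median -1.51, camera adjusted p = 2.1e-08, and 0.74 with an estimated correlation). Ccnb2 went from 2.40 ± 0.0189 to 0.213 ± 0.0439 CPM (-3.50 ± 0.48, adjusted p = 0.0043).

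Genes that mark segment 1 fell in segment 2, where the control libraries of the batches differed strongly. Lcn8 held 96458 counts in the control segment 2 library of batch 3017 and 6520 in that of batch 3097, or 23.8% and 1.5% of the control segment 1 level, and 8.88 ± 0.0513 CPM after ligation (-7.38 ± 1.34, adjusted p = 0.028; within-batch log2 ratios -8.47 and -4.48). A set of 74 genes with at least 20 CPM in control segment 1 and under 2% of that in control segment 3 was chosen after the values were seen. Their median share of the segment 1 level was 9.08% in the control segment 2 library of batch 3017 and 1.5% in that of batch 3097. In ligated segment 2, 70 of the 74 were lower than control in batch 3017 and 66 in batch 3097, and 40 were called. Initial segment genes fell in 10 of 19 and rose in 0 (13 and 1 adjusted over the list alone; median -2.0, camera adjusted p = 2.5e-05, and 0.74 with an estimated correlation). Among them were Rnase10 (-9.54 ± 1.04, 0.0067), Lcn9 (-9.11 ± 1.22, 0.013), Cst8 (-8.17 ± 1.27, 0.02), Srd5a1 (-2.0 ± 0.42, 0.033) and Ovch2 (-3.11 ± 0.36, 0.0047). ERK feedback and target genes fell in 12 of 20 and rose in 0 (16 and 0 adjusted over the list alone; median -1.67, camera adjusted p = 5.6e-08, and 0.74 with an estimated correlation). Among them were Etv5 (-6.96 ± 1.04, 0.018), Dusp6 (-2.74 ± 0.45, 0.02), Spry4 (-2.8 ± 0.58, 0.021), Spred3 (-2.44 ± 0.33, 0.0038) and Spry2 (-1.04 ± 0.13, 0.0024). Without the ligated library of batch 3017 the adjusted p was 0.14 for Lcn9, 0.17 for Etv5, 0.19 for Cst8 and Dusp6 and 0.23 for Lcn8. Adam7 fell by 1.31 ± 0.18 (0.004, and 0.071 without that library). Ros1 (-0.73 ± 0.24, adjusted p = 0.098), Etv4 (-2.5 ± 0.75, 0.094) and Gpx5 (-0.59 ± 0.18, 0.069) did not pass. Nor did Ggt1 (0.77 ± 0.41, 0.28), Lcn5 (2.58 ± 0.99, 0.16) and Rnase9 (5.86 ± 2.86, 0.26). Rnase9 held 64628 counts in the ligated library of batch 3017 and 439 in that of batch 3097.

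Among genes called in segment 2 with at least 5 CPM and the other limits of the naming rule, the largest rises were those of Nxpe2 (chromosome 9, 48318006 to 48353454; 5.96 ± 0.88, adjusted p = 0.017), Klhl14 (4.08 ± 0.77, 0.023), the contactin gene Cntn5 (3.96 ± 0.89, 0.041), and Crisp1. Stra6, the retinol transporter gene (chromosome 9, 58063788 to 58153996), rose by 3.29 ± 0.4 (0.0068). Ccdc183 (3.12 ± 0.64, 0.03), Frmpd4 (2.88 ± 0.67, 0.048) and Islr2 (2.71 ± 0.44, 0.015) followed. Nxpe2 and Stra6 were also among the genes lower in control segment 2 than in control segment 3, a comparison that uses the same control segment 2 libraries. Whether the place where the segments were divided gives these rises was not tested. Without the ligated library of batch 3017 the adjusted p was 0.15 for Klhl14, 0.11 for Islr2 and 0.066 for Stra6. Without the control library of that batch it was 0.14 for Nxpe2, 0.32 for Cntn5, 0.31 for Crisp1, 0.24 for Ccdc183 and 0.35 for Frmpd4. Tgfa rose by 1.20 ± 0.13 (0.0013) and the largest adjusted p without a library was 0.021. Ribosomal protein genes had a median of 0.29 with no member called (camera adjusted p = 2.4e-05, and 0.79 with an estimated correlation). No other list was called, with camera adjusted p-values of 0.06 to 0.98.

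In segment 3, sperm transcripts fell after ligation. Prm1 fell from 11.01 ± 5.11 CPM to 2 counts, a ratio of 423 (95% interval 117 to 3496; adjusted p = 2.3e-04), and Akap4 from 12.8 ± 3.93 CPM to 1 count, a ratio of 989.7 (177 to 39131; 2.4e-04). Of the named genes called here the largest rise was that of Isg15, an interferon-induced ubiquitin-like gene (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), from 2.15 ± 0.0182 to 5.37 ± 1.63 CPM (1.29 ± 0.22, adjusted p = 0.019). None of the other sentinel genes given here passed, apart from Prm2.

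In all 331 genes (1.7%) were called in segment 3, 60 higher and 271 lower after ligation, all with the same direction in both batches, and 254 changed at least 2-fold, 8 higher and 246 lower. DESeq2 called 642, and a fit of only these 4 libraries 211. Without the control library of batch 3017 the count was 82, and without the ligated libraries of batches 3017 and 3097 it was 70 and 132. In the fit of all groups without the segment 2 control library of batch 3017 it was 498. Of 25 named genes called, 10 kept their call whichever library was left out. Calls lost numbered 14 and 3 without the control libraries of batches 3017 and 3097, and 13 and 13 without the ligated ones.

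Germ cell and sperm genes fell in 20 of 28 and rose in 0 (the same counts adjusted over the list alone). Their median was -5.14, or -4.84 with members without counts in a group at their bound (camera adjusted p = 3.9e-25, and 0.084 with an estimated correlation). The list member Spata18 (at least 104-fold lower) had no counts after ligation, nor did Spz1 (126), Cabs1 (96.8) and Iqcf3 (64.8), which are outside the list but among the lowest genes by the naming rule. Smcp, a sperm mitochondrial protein gene (chromosome 3, 92583867 to 92588997), fell from 38.1 ± 21.8 to 0.0650 ± 0.0562 CPM (-9.09 ± 0.71, adjusted p = 0.0022, and 0.062 without the ligated library of batch 3017). Prm2 fell by 8.46 ± 0.67 (0.0026). Proliferation genes fell in 6 of 25 and rose in 0 (16 and 0 adjusted over the list alone; median -1.21, camera adjusted p = 3.3e-12, and 0.52 with an estimated correlation). Top2a, topoisomerase II alpha, changed by -2.25 ± 0.39 (0.032) and Ccnb2 by -3.25 ± 0.51 (0.013). Without the ligated library of batch 3017 their adjusted p was 0.38 and 0.17. Along the control duct Ccnb2 was highest in segment 1, at 6.72 ± 0.229, 2.40 ± 0.0189 and 1.60 ± 0.0885 CPM in segments 1, 2 and 3. Prm1 was lowest there, at 1.37 ± 0.13, 18.2 ± 4.08 and 11.01 ± 5.11 CPM.

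Interferon response genes had 1 called member of 29, Isg15, and 13 higher adjusted over the list alone (median 0.68, camera adjusted p = 3.3e-09). Macrophage genes had none called of 25, also when adjusted over the list alone (median 0.33, 0.0012). Ciliated cell genes had 1 lower of 20, and 4 lower adjusted over the list alone (median -0.75, or -0.7 with members at their bound, 8.4e-04). That member was Deup1, at -1.72 ± 0.33 (adjusted p = 0.032, and 0.38 without the control library of batch 3017). With an estimated correlation the adjusted p of these 3 lists was 0.52. Initial segment genes had 1 lower of 19 and 6 adjusted over the list alone (median -0.32, 0.0076). It was Rnase10, at -6.11 ± 0.93 (0.041, and 0.34 without the ligated library of batch 3017). The list's adjusted p was 0.32 and 0.067 without the control and the ligated library of batch 3097. ERK genes had none called of 20 and 6 lower adjusted over the list alone (median -0.83, 7.7e-04). Beta-defensins had none of 32, and 1 lower adjusted over the list alone (median 0.8, 0.032, 0.085 with library totals alone and 0.18 with the stricter low-count filter). Without the control and the ligated library of batch 3017 the list's adjusted p was 0.12 and 0.38. Ribosomal protein genes had none of 24 (median 0.28, 4.8e-07). With an estimated correlation the adjusted p of these 4 lists was 0.75. Lcn8 held 98.4 ± 5.32 CPM in control segment 3 and 5.67 ± 0.0144 CPM after ligation (-4.13 ± 1.15, adjusted p = 0.19), and Cst8 27.6 ± 1.92 and 0.922 ± 0.377 CPM (-4.87 ± 1.16, 0.14). Other rises among the named genes were those of Gar1 (1.06 ± 0.14, 0.0061), Fbxw4 (0.94 ± 0.13, 0.0079) and the RNA-binding protein gene Taf15 (0.89 ± 0.09, 9.3e-04). Hmgn3 (0.86 ± 0.15, 0.02), Hnrnpa0 (0.8 ± 0.15, 0.03) and Prr15 (0.75 ± 0.15, 0.036) followed. Of these Taf15 kept its call whichever library was left out. Without the control library of batch 3017 the adjusted p was 0.26 for Isg15, 0.097 for Gar1, 0.11 for Fbxw4, 0.35 for Hnrnpa0 and 0.38 for Prr15. Without the ligated library of that batch it was 0.2 for Hmgn3. No other list was called, with camera adjusted p-values of 0.079 to 0.95.

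**Figure D2:**
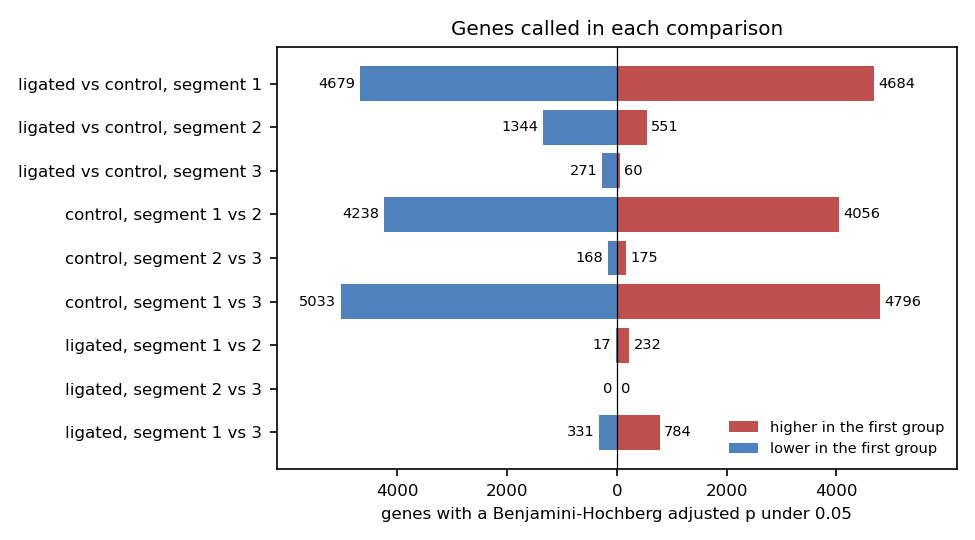
Number of genes called at an adjusted p under 0.05 in each comparison (edgeR, 2 libraries per group); bars to the right are genes higher in the first group named, bars to the left genes lower. Ligation calls drop from 9363 in segment 1 to 1895 in segment 2 and 331 in segment 3, and the ligated segments 2 and 3 have no called difference in this fit of all groups.

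The control segments give the background of regional expression. Segment 1 differed from the others: 8294 genes (43.2%) were called between control segments 1 and 2, 4056 higher in segment 1 and 4238 lower, and 9829 (51.2%) between segments 1 and 3, 4796 higher and 5033 lower. Between segments 2 and 3 the count was 343, 175 higher in segment 2 and 168 lower. Genes in this paragraph are the extremes within the naming rule, among called genes of at least 5 CPM, and some genes below that level or with predicted names had larger fold changes. Highest in segment 1 over segment 3 were Ntsr1 (8.66 ± 0.52, adjusted p = 2.5e-04), Xkr7 (8.51 ± 0.86, 0.0016), AC132367.1 (8.34 ± 0.98, 0.0032), the lectin gene Clec18a (8.16 ± 1.22, 0.0029) and the metalloprotease gene Adam28 (7.94 ± 1.43, 0.0058). Lowest were Gldn (0 and 2 counts in segment 1, ratio 1775, 95% interval 491 to 14666), Adtrp (no counts in segment 1, at least 62.3-fold lower), Defb15 (-8.51 ± 1.55, 0.0065), Nxpe5 (-7.93 ± 1.23, 0.0031) and Spink11 (-7.82 ± 1.61, 0.01). Highest in segment 1 over segment 2 were Prss33, a serine protease gene (1 count in segment 2, ratio 369, 95% interval 65.9 to 14602), Ffar2 (8.01 ± 0.4, 2.0e-05), Nxph4 (7.96 ± 1.07, 0.0024), Myo16 (7.88 ± 0.53, 6.1e-05) and Dpys (7.8 ± 0.76, 1.4e-04). Lowest were Gldn (ratio 233, 95% interval 64.0 to 1930), the pancreatic polypeptide gene Ppy (-6.47 ± 0.97, 0.0036), Lypd8 (-6.36 ± 1.69, 0.029), Hhatl (-5.94 ± 0.98, 0.0053) and Kcnj5 (-5.75 ± 0.79, 8.1e-04). Between segments 2 and 3 the citrate transporter gene Slc13a2 (3.21 ± 0.55, 0.044), P4ha2 (2.97 ± 0.45, 0.044), Hapln3 (2.85 ± 0.47, 0.032), Cebpb (2.56 ± 0.40, 0.043) and Wfdc2 (2.26 ± 0.43, 0.049) were higher in segment 2. Nxpe2 (-6.17 ± 0.88, 0.043), the neuropeptide Y gene Npy (-5.02 ± 0.73, 0.032), Stra6 (-2.77 ± 0.4, 0.036), Elf5 (-2.6 ± 0.45, 0.038) and Rprml (-2.57 ± 0.48, 0.043) were lower.

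By list, between control segments 1 and 3 the ERK genes were higher in segment 1 in 18 of 20 and lower in 2. Proliferation genes were higher in 19 of 25 and lower in 1, and cholesterol synthesis genes higher in 16 of 22 and lower in 3. Endothelial genes were higher in 12 of 15 and lower in 0, and germ cell genes lower in 25 of 28 and higher in 1. Adjusted over the list alone the higher and lower counts were 18 and 2, 23 and 1, 16 and 3, 12 and 0, and 1 and 25. The count between segments 1 and 2 was 4749 without the segment 1 library of batch 3017, and 5046 in a fit of only those 4 libraries. The count between segments 2 and 3 changed most with single libraries. It was 57 and 2384 without the segment 2 libraries of batches 3017 and 3097, and 78 and 0 without the segment 3 libraries of those batches. It was 0 without the batch block, 162 in a fit of only those 4 libraries and 1589 with DESeq2. Library totals alone, in place of TMM, changed its split to 135 higher and 215 lower.

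The same pairs were compared after ligation. Between ligated segments 2 and 3 no gene was called by edgeR in the fit of all groups (1344 had an unadjusted p under 0.05, where 961 are expected by chance, and DESeq2 called 30). The smallest adjusted p was 0.37. These libraries deviated alike within a batch, with a correlation of 0.72 against -0.02 to 0.45 for the other pairs of groups. A fit of only these 4 libraries called 1080 genes, more than the 162 that such a fit called between control segments 2 and 3. Between ligated segments 1 and 2, 249 genes were called, 232 higher in segment 1 and 17 lower, and between ligated segments 1 and 3, 1115, 784 higher and 331 lower. The genes higher in ligated segment 1 than in ligated segment 3 included 20 of 25 proliferation genes, 14 of 20 ciliated cell genes, 11 of 25 macrophage genes, 9 of 15 endothelial genes and 7 of 13 complement genes. No member of these lists was called lower. Adjusted over the list alone the counts were 22, 15, 13, 13 and 8. None of the 19 initial segment genes and 20 ERK genes was called, also when adjusted over the list alone.

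Of the 8294 genes called between control segments 1 and 2, 154 (1.86%, 95% interval 1.58 to 2.17) were called in the same direction between the ligated segments, and 8 in the opposite direction. For segments 1 and 3 the share was 629 of 9829 (6.4%, 5.92 to 6.9), with 123 opposite, and for segments 2 and 3 it was 0 of 343 (upper limit 1.07%). These intervals treat genes as independent and leave out the spread between libraries. Part of any shrinkage of the segment differences can follow from choosing genes on the control libraries. The median absolute log2 difference over these genes went from 0.93 to 0.16, from 1.03 to 0.22 and from 0.73 to 0.18 in that order. The slope of ligated on control differences was 0.13 ± 0.057 for segments 1 and 2 (SD of 2 batches; 0.089 and 0.17), 0.139 ± 0.026 for segments 1 and 3 (0.121 and 0.158) and 0.217 ± 0.054 for segments 2 and 3 (0.255 and 0.179). In a check added after the results were seen, genes at least 2-fold apart in 1 batch of control libraries and with at least 5 CPM were measured in the other batch. Slopes on the first batch were then 0.974 and 0.785 in control and 0.117 and 0.062 in ligated tissue for segments 1 and 2, with genes chosen in batches 3017 and 3097 in turn. For segments 1 and 3 they were 0.915 and 0.984 in control and 0.122 and 0.141 in ligated tissue. For segments 2 and 3 they were 0.531 and 0.876 in control and 0.042 and 0.327 in ligated tissue. The count between ligated segments 1 and 2 moved with single libraries, to 7 without the segment 1 library of batch 3097, and to 2 and 0 without the segment 2 libraries of batches 3017 and 3097. That between ligated segments 1 and 3 was 534 and 35 without the segment 1 libraries and 15 and 281 without the segment 3 libraries of those batches. Without the batch block the counts were 112 and 577, with DESeq2 515 and 1706, and in the fit of all groups without the segment 2 control library of batch 3017 they were 626 and 2059. In fits of only the libraries compared, 1194 genes were called between ligated segments 1 and 2 and 1080 between ligated segments 2 and 3. Library totals alone gave 1196 higher and 226 lower between ligated segments 1 and 3. In those settings the share kept for segments 1 and 2 was 1.05% without the block, 3.94% with DESeq2, 4.57% without the segment 2 control library of batch 3017 and 11.69% with only the libraries compared. For segments 2 and 3 it was 35.33% in that last fit and 1.13% with DESeq2. For segments 1 and 3 it was 10.44% with only the libraries compared, 11.41% without the segment 2 control library of batch 3017, 10.06% with DESeq2 and 4.26% without the block. Leaving out single libraries gave 0% to 2.22% for segments 1 and 2 and 0.12% to 7.64% for segments 1 and 3.

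**Figure D3:**
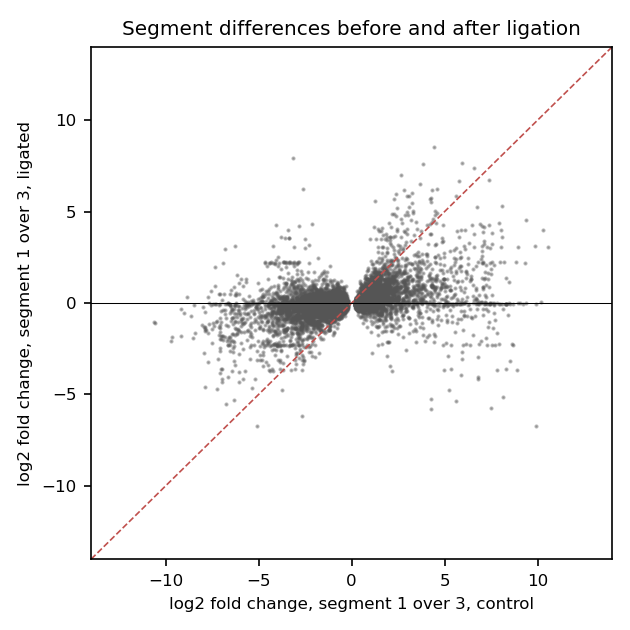
Log2 fold change of segment 1 over segment 3 in control tissue (horizontal axis) and in ligated tissue (vertical axis) for the 9829 genes called between these control segments, each point a gene. The dashed line marks equal differences. The slope of 0.139 given in the text is the mean of 2 slopes from within-batch log2 ratios (0.121 and 0.158), not that of the fitted values plotted.

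The ligation effect itself was compared between segments. It differed between segments 1 and 2 in 3561 genes, 1986 with a higher and 1575 with a lower log2 fold change in segment 1, and between segments 1 and 3 in 5907 genes, 3088 higher and 2819 lower. Between segments 2 and 3 no gene was called by edgeR (1917 at an unadjusted p under 0.05, 961 expected by chance, 167 with DESeq2). Lcn8, Cst8 and Lcn9 fell more in segment 1 than in segment 3, with differences of -5.84, -5.45 and -7.18 on the log2 scale, while between segments 1 and 2 the difference did not pass for Lcn8 (-2.59 ± 1.49, adjusted p = 0.29), Cst8 (-2.16 ± 1.44, 0.36) or Lcn9 (-4.13 ± 1.43, 0.1). Each of these differences also equals the segment difference in ligated tissue minus that in control tissue. It therefore depends on the level a gene had in control tissue. Lcn8 held 13700 and 14200 CPM in control segment 1 and 94.6 and 102 CPM in control segment 3. After ligation it held 15.5 and 12.9 CPM in segment 1 and 5.68 and 5.66 CPM in segment 3. A larger difference is thus not by itself a stronger response to ligation. Crisp1 fell in segment 1 and rose in segment 2, a difference of -10.01 ± 1.19 (adjusted p = 0.005). The count for segments 1 and 2 was 1614 and 2325 without the control segment 1 libraries of batches 3017 and 3097, 1767 without the ligated segment 1 library of batch 3017, 1784 and 1703 without the ligated segment 2 libraries of those batches, and 2255 without the batch block. That for segments 1 and 3 was 3909 without the control segment 3 library of batch 3017 and 3835 without the ligated segment 1 library of that batch, and library totals alone split it 4044 to 1815. That for segments 2 and 3 was 1124 without the control segment 2 library of batch 3097.

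Genes called by ligation overlapped between segments. The segments share no control libraries, but they share batches and an estimate of the spread, and whether they share mice is not given. The counts for independent lists given here leave this out. Segments 1 and 2 shared 435 genes higher after ligation, where independent lists would share 134.3, and 891 lower (327.3 for independent lists), with 56 called in opposite directions. Segments 1 and 3 shared 17 higher (14.6) and 136 lower (66.0), with 27 opposite, and segments 2 and 3 shared 15 higher (1.7) and 264 lower (19.0), with 0 opposite. In all 3 segments 11 genes rose and 135 fell, Prm1 and Prm2 among the latter. Summed over directions, segments 1 and 2 shared 1326 genes, 471 and 2935 without the control segment 2 libraries of batches 3017 and 3097, and 107 and 238 without the ligated segment 2 libraries. The count was 771 without the batch block and 93 in fits of only the libraries compared. Segments 1 and 3 shared 153, but 58 without the control segment 3 library of batch 3017, 84 without the ligated segment 1 library of batch 3017, and 55 and 86 without the ligated segment 3 libraries. The count was 279 with DESeq2, 247 without the segment 2 control library of batch 3017 and 76 in fits of only the libraries compared. Segments 2 and 3 shared 279, but 82 without the control segment 3 library of batch 3017, 110 and 172 without the ligated segment 2 libraries, and 69 and 112 without the ligated segment 3 libraries. The count was 451 with DESeq2 and 68 in fits of only the libraries compared.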

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

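The tests of the 3 patterns weighed here were chosen only after the results they measure were seen. The differences in ligation effect between segments come from the contrasts planned before.

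The ligation effect differed between segments 1 and 2 in 3561 genes and between segments 1 and 3 in 5907, by the test of the difference itself. For segments 2 and 3 that test called 0 genes with edgeR, 1917 at an unadjusted p under 0.05 and 167 with DESeq2. Values are log2 fold changes by ligation in segment 1 minus those in the other segment. Such a value also depends on how far the control segments differ, so a larger one is not by itself a stronger response to ligation. For genes without counts in a group, or with only a few, the fitted value depends on the prior count and gives no bound. Against segment 2, the sentinel genes that passed were Ros1 (-1.38), Etv4 (-7.37), Dusp6 (-3.01), Crisp1 (-10.01), Ggt1 (2.59) and Gpx5 (0.83). By the naming rule the highest were Spata18 (8.92), Adtrp (8.23), Hspb9 (7.26), Irgc1 (6.49) and Pgk2 (6.39), and the lowest Defb48 (-8.55), Spo11 (-8.47), Nxph4 (-8.47), Acoxl (-7.81) and Crisp1.

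Against segment 3, the sentinel genes that passed were Ros1 (-2.15), Cst8 (-5.45), Lcn8 (-5.84), Lcn9 (-7.18), Etv4 (-7.74), Etv5 (-5.64), Dusp6 (-4.65), Spry4 (-3.60), Srd5a1 (-2.12), Crisp1 (-6.76), Ggt1 (3.20) and Prm1 (3.81). By that rule the highest were Spata18 (11.08), Gldn (9.61), Adtrp (9.48), Lypd8 (7.60) and Pate4 (7.0), and the lowest Ffar2 (-11.48), Prss33 (-9.86), Vip (-9.74), Nxph4 (-9.45) and Acoxl (-9.16).

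Transcripts of segment 1 were found in the control segment 2 libraries, more in batch 3017, and fell in ligated segment 2. Segment 1 tissue of average make-up would bring all of them at 1 share of their segment 1 level. Over all 74 genes the median share was 9.08% in batch 3017, where the 10th percentile was 0.839%. In batch 3097 it was 1.5%, where the 10th percentile was 0.374%. Both medians lay above 3 times the 10th percentile, which argues against 1 common share. Of the 40 genes that fell, 32 lay above that limit in batch 3097 and 35 in batch 3017. These 40 were called partly on their level in the same control libraries, so their counts add no support. A batch difference alike in every group is argued against by control segment 1, where the same genes differed by 0.17 log2 against 2.48 in control segment 2, or 6.69%. A border between segments placed closer to segment 1 in batch 3017 may account for the excess there. The 314 genes higher in control segment 3 were shifted by a median of -0.71 beyond the mean of control segment 1 and the ligated groups. Of these, 280 were lower than that mean. Control segment 1 itself differed by -0.52 between batches, a direction that such a border would also give. A true response of segment 2 to ligation stays open beside such a border. In batch 3097, 66 of the 74 segment 1 genes were also lower after ligation, but this cannot decide between them. Genes of this set such as Lcn8, Cst8 and Lcn9 also fell in ligated segment 1. Segment 1 tissue would therefore bring them into control but hardly into ligated libraries of segment 2.

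Germ cell transcripts fell in ligated segments 2 and 3 and were low in control segment 1, where 24 of the 28 list members were called lower than in control segment 2 and 1 higher. Library size is argued against, since summed totals differed by 1.21-fold in segment 2 while the 20 members called lower in both segments had a median fold of 157 there, and the whole list a median of -5.33 log2 with members without counts at their bound. The 16 of these 20 with ligated levels under 10% of control kept nearly 1 ratio between control groups, with a median of -3.91 and an SD of 0.43 log2 for segment 1 over 2 and an SD of 0.22 for segment 3 over 2, which is consistent with a single source such as germ cells or sperm carried in the duct. Testis tissue in the control libraries cannot be told apart from it: 0 of 10 testis somatic genes were called higher in both control segments, but the Leydig cell gene Insl3 had 11 and 4 counts in control segment 2 and 9 and 10 in ligated segment 2, too few to decide. Star had 17 and 23 against 27 and 22 counts there and 20 and 23 against 19 and 25 in segment 3, and Hsd3b6 and Hsd17b3 had none in these 8 libraries. Cyp17a1 had 62 and 74 against 245 and 149 counts in segment 2 and 115 and 314 against 411 and 317 in segment 3, unscaled. None of these shows a clear rise in control tissue, but those with counts are also found in ligated tissue, and the share that testis tissue would need was not measured. Of the germ cell list 5 of 28 members, and of the testis somatic list 6 of 10, held at least 1 CPM in each ligated group.

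Part of the listed genes of ciliated cells, which line the efferent ducts, were called higher in ligated segment 1. With an estimated correlation the camera adjusted p of the list was 0.66. Efferent duct tissue in larger amount would lift all members by 1 ratio. A set of 9 members was chosen for a mean level in segments 2 and 3 far below that in ligated segment 1. For these 9, more of such tissue cannot be told apart from a change in segment 1 itself. All 9 were higher than in control segment 1, by a median of 1.24 (0.04 to 1.77), but with an SD of 0.52 and 3 called. The choice used the level in ligated segment 1, which favours a rise, so that all 9 were higher adds no support. For the 7 risen members not so far lower in segments 2 and 3 it cannot be told apart either. Ligated segment 1 stood at a median of 1.2 times the other segments (0.689 to 3.9), but 4624 other risen genes chosen alike had a median of 1.02, so the way they were chosen keeps this ratio low. Of the list 8 of 20 members held at least 1 CPM in each ligated group.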

How the results depend on the processing

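The fit of all groups without the segment 2 control library of batch 3017 was chosen after seeing the data. Counts within 1.5 times the value reported are taken as the same, and so are shares kept that lie inside the 95% interval of the share reported. That interval treats genes as independent, so a share outside it can still lie within the spread between libraries. For each change below the cause was not tested, except that a minimum of 1 log2 can only lower counts.

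With RLE size factors or abundant genes left out of library sizes, every count and share stayed within those limits, as did all 102 list results. Library totals alone moved the share kept for segments 1 and 3 from 6.4% to 7.49%. No low-count filter gave 1 gene for the difference between segments 2 and 3, 2.76% kept for segments 1 and 2, and 9 lists in segment 2. The stricter filter gave 155 genes between ligated segments 1 and 2 and 1.28% kept. It ended the list calls of macrophages in segment 1 (adjusted p = 0.076) and beta-defensins in segment 3 (0.18), and added lipocalins (0.038) and fibroblasts (0.042) in segment 3.

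A minimum of 1 log2 gave 4396 and 1068 genes for ligation in segments 1 and 2, 3935, 117 and 5042 for control segments 1 and 2, 2 and 3, and 1 and 3, 659 for ligated segments 1 and 3, 1933 and 3289 for the differences of segment 1 from 2 and 3, and 627 shared by segments 1 and 2. Control differences of at least 1 log2 were kept in 3.07% and 9.18% for segment 1 against 2 and 3.

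Without the replicate block (batch) there were 1162 genes for ligation in segment 2, 0 between control segments 2 and 3, 112 and 577 between ligated segment 1 and segments 2 and 3, 2255 for the difference between segments 1 and 2, 771 shared by them, and 1.05% and 4.26% kept. With only the libraries compared there were 149 and 211 genes for ligation in segments 2 and 3, 5046 and 162 between control segments 1 and 2 and 2 and 3, 1194 and 1080 between the same ligated pairs, 93, 76 and 68 shared by segments 1 and 2, 1 and 3, and 2 and 3, and 11.69%, 35.33% and 10.44% kept for pairs 1 and 2, 2 and 3, and 1 and 3.

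Without the segment 2 control library of batch 3017 there were 498 genes in segment 3, 626, 5 and 2059 between ligated segments 1 and 2, 2 and 3, and 1 and 3, 247 shared by segments 1 and 3, and 4.57% and 11.41% kept. DESeq2 gave 642 in segment 3, 1589 between control segments 2 and 3, 515, 30 and 1706 between the ligated pairs, 167 for the difference between segments 2 and 3, 279 and 451 shared by segment 3 with 1 and 2, and 3.94%, 1.13% and 10.06% kept.

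With an estimated correlation 0 lists were called in each segment, against 13, 5 and 9. Fry called 21 in segment 1 and 1 in segment 3.

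Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 6250 to 7586, 148 to 4066 and 70 to 395 genes for ligation in segments 1, 2 and 3. Control pairs 1 and 2, 2 and 3, and 1 and 3 gave 4749 to 8214, 0 to 2384 and 6887 to 7881. The ligated pairs gave 0 to 192, 0 to 1 and 15 to 534, and the differences in effect 1614 to 4655, 0 to 1124 and 3835 to 5006. Shared genes were 107 to 2935 for segments 1 and 2, 55 to 157 for 1 and 3 and 69 to 279 for 2 and 3. The shares kept were 0% to 2.22% for segments 1 and 2 and 0.12% to 7.64% for 1 and 3. Lists called were 11 to 14, 5 to 8 and 8 to 11.

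Of the named genes, none of them called, 8 values changed sign without a library; ranges over the libraries left out follow. Rnase9 ranged from -0.83 to 0.48 and Gpx5 from -0.01 to 0.49 in segment 1, and Rnase9 from -0.68 to 7.31 in segment 2. In segment 3 Ros1 ranged from -0.10 to 0.22, Srd5a1 from -0.87 to 0.18, Ggt1 from -0.21 to 0.48 and Crisp1 from -0.50 to 1.95, with -0.42 as its other negative value. Otherwise 3228 values of named genes across all alternatives kept direction and side of the threshold, 412 lost and 32 gained a call. For lists the numbers were 1290, 49 and 45. Changes under the floor of 3 counts, 0.071 to 0.098 CPM, were not detectable at this depth.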

Other observations

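The test in the last paragraph was chosen before its result was seen. The genes of the next paragraph were chosen after their values were seen.

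Vip, which encodes vasoactive intestinal peptide, held 23.1 CPM in control segment 1 and 0.0257 CPM after ligation (log2 fold change -9.62 ± 0.58, adjusted p = 1.5e-05), with at most 0.455 CPM in the other groups. Ppy went from 0.430 to 20.2 CPM in segment 1 (5.7 ± 0.97, adjusted p = 0.0047) and lay between 24.1 and 41.7 CPM elsewhere. Npy was highest in segment 3, at 10.2 CPM in control and 14.9 CPM in ligated tissue, and rose in segment 1 from 0.129 to 1.48 CPM (3.61 ± 0.88, adjusted p = 0.012). Klrb1c, a gene of the T and NK cell list, fell in segment 1 from 489 to 10.5 CPM (-5.5 ± 0.8, adjusted p = 0.0026), while that list as a whole was not called.

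One hypothesis is that ligated segment 1 takes on the levels of control segment 3. Genes at least 2-fold apart between these control segments were chosen in 1 batch and measured in the other, on a scale where 0 is control segment 1 and 1 is control segment 3. The median position of ligated segment 1 was 0.86 over 2598 genes chosen in batch 3017 and 0.97 over 2371 genes chosen in batch 3097, with 84.6% and 92.8% of genes past 0.5. Both medians were past 0.5, so the median gene lay nearer to control segment 3 than to control segment 1. The measure also counts genes that went past control segment 3, such as Lcn8, Cst8 and Lcn9. Control segment 2 was not tried as the target. For the 1347 and 1181 genes higher in control segment 3 the medians were 0.83 and 0.94. For the 1251 and 1190 genes higher in control segment 1 they were 0.89 and 0.99. These values argue against a fall of segment 1 genes alone. Without control segment 2 as a target, the test cannot tell a move to segment 3 levels from a move away from segment 1 levels in general. A change in the mix of cell types stays open.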
